A study of Homo sapiens with 17 samples.

How the data were processed

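Single-cell RNA was measured in 17 libraries of human skin cells: 4 from lesional and 5 from non-lesional skin of people with atopic dermatitis, 7 from frozen healthy skin and 1 from fresh healthy skin. Per the labels' protocols, biopsies were thawed, dissociated in Liberase and then in trypsin, made into libraries with the 10x Genomics Chromium 3' kit of version 2 and sequenced on an Illumina HiSeq. STAR and hg38 are named in the submitters' processing notes, with no version or role.

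The deposited files hold, for each cell, the natural log (ln) of 1 + UMIs per 10000 of the UMIs over the genes listed in that file, and the values were not scaled across cells. The files list no mitochondrially encoded gene, so the filters on mitochondrial share set before the data were examined had no effect. Dividing each cell's back-transformed values by its smallest one gave whole numbers for 100.0% of the nonzero values within a tolerance of 0.01, and these were taken as UMI counts (70678493 UMIs in 45332 cells). The files listed 18524 genes in any library and 8403 in every library, and a gene not listed in a library was taken as 0 there.

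Donor-sex genes were removed, which left 18502 genes. Cells with at least 200 genes were kept (39600, of which 35169 were frozen). Scrublet in scanpy called 61 cells doublets (0.154%), under the 0.5% below which the caller was held not to have worked, so no cell was removed. Values were scaled to 10000 UMIs per cell and logged, 2000 variable genes were chosen per library, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (seed 0) gave 28 clusters. A cluster was named for the class with the highest mean z-score over markers fixed before the data were examined, among classes with at least 3 markers detected. This last condition was moved ahead of the ranking after the clusters were seen, and naming by the rule as first fixed was added as an alternative. Each class is thus keratinocyte-like, fibroblast-like and so on by its markers, and is called by the plain name. The rule left 2 clusters (145 cells, 0.366%) unnamed, and 88.6% of named cells had the same class by the highest marker score per cell. Fibroblasts, T and NK cells, myeloid cells and keratinocytes were sub-clustered at resolution 0.5, leaving out genes with an unadjusted p under 0.05 in that class. This was 1 of 3 ways tried after shares had been seen, and the other ways are given as alternatives.

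UMIs were summed per library and class for libraries with at least 20 cells of the class, and a class was compared only with at least 3 such libraries in each group. Genes needed, in as many libraries as the smallest group, the CPM that 10 UMIs give in a library of median size, and a total of at least 15 UMIs. Library sizes were scaled by a trimmed mean of M values, with 30.0% of M and 5.0% of A trimmed. The test was limma on log2(CPM + pseudocount), with a pseudocount worth 2 UMIs in a library of mean size, a variance trend, the 3 groups in 1 fit, and Benjamini-Hochberg adjustment over the genes tested, at 0.05. All log2 fold changes are on this scale, which understates the change of low genes. The test first fixed was a count model. The files hold ln values, so edgeR and DESeq2 were not run, though the recovered UMIs would allow them, and limma took their place. limma voom was written first and its counts on the real libraries were seen. After that, 5 limma fits were compared, and the fit with the variance trend was taken for its error control in simulated data. Simulated results are given for that fit alone, so fewer false calls than by voom are not shown here. That fit also often gave fewer calls, and the other 4 fits are given as alternatives. With 200 simulated changes per class, at 2- and 4-fold, it recovered 3% and 73.5% in keratinocytes (5309 genes), 3.5% and 68% in fibroblasts (8513), 12% and 81% in vascular endothelium (9366), 0% and 68% in mural cells (4769), 0% and 60% in T and NK cells (3918) and 0% and 25.5% in myeloid cells (6222). False calls were 0% to 4.71% of calls, but 11.1% (3 of 27) in endothelium at 2-fold.

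Gene lists (45, making 241 pairs of list and class) were fixed before the data were examined. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and limma's fry as alternatives, and adjusted within each contrast. Shares of cells were compared by 2-sided exact permutation tests over libraries, adjusted over the classes or sub-clusters of a contrast. For the share of fibroblasts with COL6A5 and COL18A1, each cell was thinned to 1000 UMIs and shallower cells were left out. Genes were named by a rule fixed before the data were examined: per class and contrast, the 8 with the largest rise and the 8 with the largest fall among those past the threshold with an average log2 CPM of at least 5 and the same direction in every library of the first group; up to 4 members per list with the smallest p; the 5 with the smallest p where fewer than 5 passed; and COL6A5, COL18A1, CCL2 and CCL19 in fibroblasts, IL13 and IL22 in T and NK cells and LAMP3 and CCR7 in myeloid cells. Genes of sex, genotype or receptor segments were not named. Of the genes the rule gave for a list, the text prints those of the lists past the threshold. A few genes the rule named are not reported here. A fold against a group at 0 UMIs is a lower bound, set against 3 UMIs over the group.

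The fresh library stayed out of the comparisons because its handling differed and because the 8 healthy libraries came from fewer donors. The alternatives left out each library in turn and changed the scaling, the low-count filter, the pseudocount, the fit, the depth term, the cell minimum, the doublet filter, the way cells are classed, the healthy group and the clusters used, the thinning and the sub-clustering. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.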

Results

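Cells of human skin were profiled by droplet 3' RNA sequencing with unique molecular identifiers (UMIs). Lesional skin of people with atopic dermatitis gave 4 libraries, their non-lesional skin 5, and the skin of healthy controls 7 frozen libraries and 1 fresh library. The frozen libraries held 10433 lesional, 7035 non-lesional and 23124 healthy cells as deposited. Total UMIs per library ran from 2797162 to 6569185 in lesional skin, from 233659 to 3188884 in non-lesional skin and from 391417 to 8501344 in frozen healthy skin, and the fresh library had 15485094. Libraries carry the sample numbers of the labels (8 for the fresh one). Intervals and limits cover counting error only. Fold changes are log2 values ± SE from limma on CPM per library and class, and levels are mean CPM ± SD over libraries. For gene lists, counts are given over all genes tested and adjusted within the list, and values in brackets after a fold change are adjusted p. In the frozen healthy libraries 4, 9, 12 and 17 the summed level of 20 HOX genes, which mark position along the body, was 8.91, 4.76, 0 and 0 CPM in fibroblasts, against 144 to 802 CPM in the other libraries.

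Shares of cell types bear on the immune enrichment that the series title names. Myeloid cells (macrophages and dendritic cells) made up 12.2% ± 3.27 (SD, n = 4) of lesional cells and 2.57% ± 1.15 (SD, n = 7) of healthy cells. All 4 lesional libraries (at least 9.41%) lay above all 7 healthy ones (at most 3.68%). T and NK cells were 17% ± 7.71 of lesional and 8.79% ± 6.75 of healthy cells, and vascular endothelium 20.9% ± 7.78 and 33.0% ± 9.86. In non-lesional skin (n = 5) myeloid cells were 6.50% ± 6.75 and T and NK cells 13.3% ± 15.8 of the cells. By 2-sided exact permutation tests over 11 classes, the myeloid share was higher in lesional than in healthy skin (p = 0.00303, the smallest these 11 libraries can give, adjusted p = 0.0333, difference 9.67 points). Of the 33 shares tested over the 3 contrasts it was the single share past the threshold. T and NK cells (exact p = 0.10, adjusted p = 0.367, higher in 3 of 4 lesional libraries) and vascular endothelium (exact p = 0.0788, adjusted p = 0.367, lower in 4 of 4) did not pass in lesional against healthy skin. Nor did myeloid cells in non-lesional against healthy skin (exact p = 0.101, adjusted p = 0.370, higher in 4 of 5) or in lesional against non-lesional skin (exact p = 0.159, adjusted p = 0.883). Among immune cells alone, the myeloid share was 43.7% ± 10.3 in lesional, 34.5% in non-lesional and 27.9% ± 15 in healthy skin (exact p = 0.106 for lesional against healthy skin). The adjusted myeloid call was lost with any 1 of the 11 libraries left out, the smallest possible p being larger, while the difference stayed between 8.36 points (without lesional 2) and 10.6 points (without lesional 5). Without the 4 healthy libraries low in HOX genes it was 9.66 points (adjusted p = 0.157). The non-lesional T and NK share was 4.49 points above healthy skin and -2.24 without non-lesional 16.

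**Figure D1:**
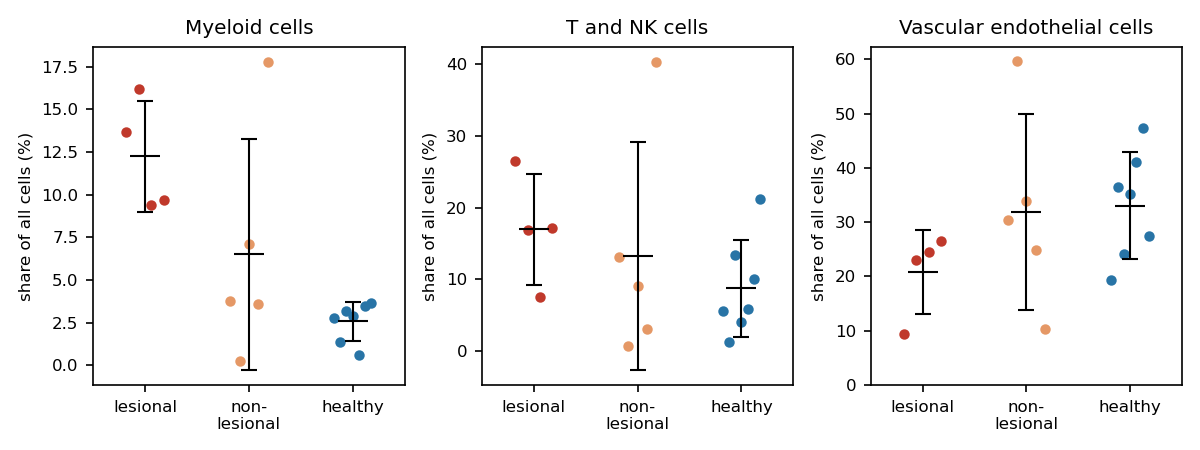
Share of cells (percent, y axis) of each cell class in lesional, non-lesional and healthy frozen skin, with 1 dot per library and a black bar at the mean ± SD. The 4 lesional libraries hold 9.41% to 16.2% myeloid cells and the 7 healthy libraries 0.623% to 3.68%.

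Fibroblasts of lesional skin were set against those of healthy skin, a comparison that bears on the fibroblast population named in the series title. COL6A5, a chain of collagen VI, rose by 5.59 ± 0.89 on the log2 scale, from 8.37 ± 15.4 CPM in 7 healthy libraries to 335 ± 189 CPM in 4 lesional libraries. CCL26, the eotaxin that draws eosinophils, rose from 2.30 ± 3.70 to 96.8 ± 48.0 CPM. TNFAIP6 rose from 28.3 ± 25.8 to 514 ± 193 CPM, and PCOLCE2 from 29.2 ± 38.8 to 234 ± 129 CPM. The metallothionein MT2A rose from 919.6 ± 465 to 3445 ± 1638 CPM. Of 8513 genes, limma called 25 at an adjusted p of 0.05 (259, 256, 470.0 and 614 by limma voom, its robust form, voom with library weights and limma with library weights, the other 4 fits, in this order throughout), 19 higher and 6 lower, and 959 were nominal (unadjusted p below 0.05). Fibroblasts of the groups sat in different clusters, and shifts between kinds of fibroblast were not separated from changes within them: pooled, the cluster led by STMN2, DPT and PTGDS, 74.6% of it from healthy 4, held 52.6% of healthy and 3.42% of lesional fibroblasts, that led by TNFAIP6 and PCOLCE2 3.32% and 32.3%, and that led by COL6A5 and TNC 2.01% and 22.5%. Adjusted p was 0.00964 for TNFAIP6 (log2 4.55 ± 0.66) and CCL26 (4.41 ± 0.65), 0.0159 for COL6A5 and 0.0463 for PCOLCE2 (3.34 ± 0.69) and MT2A (1.91 ± 0.39), each higher in 4 of 4 libraries. Also higher were TPPP3 (2.06), FILIP1L (2.45), TUBB2A (1.80), NAMPT (1.77), KPNA2 (1.75) and MT1M (1.63). Among the lower ones were BHLHE41 (-1.80), CNTFR (-1.75), MRPS6 (-1.57), HMGB2 (-1.34) and RUNX1T1 (-1.28), with adjusted p between 0.0257 (CNTFR) and 0.0463.

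The type 2 cytokine response, the genes that IL4 and IL13 induce, rose as a group in lesional against healthy fibroblasts. Of 12 measured members 2 rose over all genes tested and 6 within the list, with a median log2 of 1.24 (camera in limma, adjusted p = 1.39e-08; 0.0140 with an estimated correlation, the order used for all lists). Over all classes, 34 list calls were made for lesional against healthy skin, 16 for non-lesional against healthy and 19 for lesional against non-lesional skin; 3 of these held with an estimated correlation, this one and the keratinocyte markers in keratinocytes of lesional and of non-lesional against healthy skin. Members that did not pass were POSTN, a matrix protein (2.74, adjusted p = 0.0550), and TNC, a matrix glycoprotein of wounds (3.12, adjusted p = 0.150). The metallothioneins shifted up, with 2 of 7 past over all genes and 4 within the list, a median of 1.49 (adjusted p = 8.57e-06; 0.168). MT1A stood at 2.66 (adjusted p = 0.0818). Reads of MT1 genes can be shared between paralogs. Collagens had 1 of 23 past and 5 within the list, median 0.62 (adjusted p = 3.01e-05; 0.213). Among them COL6A6 stood at 2.72 (0.238), COL6A3 at 1.0 (0.154) and COL6A2 at 0.92 (0.150). Chemokines and cytokines had 1 of 15 past and 4 within the list, median 0.72 (adjusted p = 0.000350; 0.423). CXCL1 stood at 3.55 (adjusted p = 0.0893) and IL32 at 3.19 (0.184). Genes of the reticular dermis had 1 of 12 past and 5 within the list, median 0.85 (adjusted p = 0.000551; 0.417). The fibrillin FBN1 stood at 1.57 (0.113) and MFAP5 at 1.27 (0.150). Genes of the papillary dermis had none of 11 past, 1 higher and 1 lower within the list, median 1.27 (adjusted p = 0.0249; 0.530). PDPN stood at 1.78 (0.0990) and PTGDS at -3.27 (0.169). Immediate early and heat shock genes, a sign of handling, had none of 16 past in either way and a median of 0.53 (adjusted p = 0.0257; 0.530). JUND stood at 0.87 (0.238). The 4 genes the study is known for were chosen on these samples and are not independent evidence: 1 passed over all genes and 3 within the list, median 1.5 (adjusted p = 0.000435; 0.167). COL18A1 stood at 1.27 ± 0.49 (adjusted p = 0.329), CCL2 at 1.74 (0.334) and CCL19 at 1.27 (0.657, higher in 3 of 4 libraries).

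The count of 25 fibroblast genes moved with single libraries: none without lesional 1, 2 without lesional 5, 4 without lesional 2, healthy 9 or healthy 12, 8 without healthy 17, 11 without healthy 10, 38 without lesional 7, 50 without healthy 4 and 67 without healthy 6. TNFAIP6 and CCL26 lost their call without lesional 1 alone (adjusted p = 0.0944 and 0.110), COL6A5 without lesional 1 (0.110) and lesional 5 (0.122), and the others named above kept theirs in 2 (BHLHE41) to 7 (CNTFR) of the 11 fits. Every one of the 25 calls was lost with the log2 median UMIs per cell as a covariate or a pseudocount of 0.5 UMIs, and without the 4 healthy libraries low in HOX genes 14 genes passed. List calls lost in single fits were those of immediate early genes without healthy 13 or 17 or lesional 5 or 7 (adjusted p = 0.0594 to 0.202) and papillary genes without healthy 4, 6 or 13 or lesional 5 or 7 (0.0661 to 0.218).

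**Figure D2:**
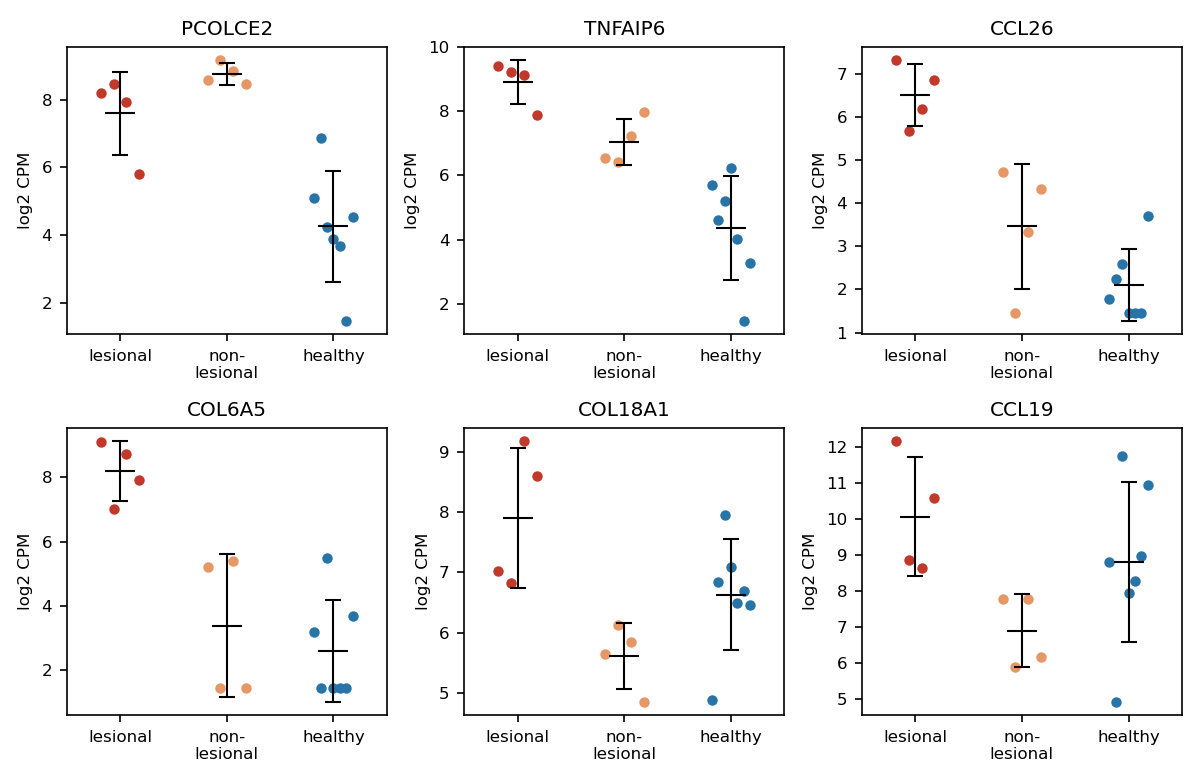
Level per library (log2 CPM, y axis) of PCOLCE2, TNFAIP6, CCL26, COL6A5, COL18A1 and CCL19 in fibroblasts of lesional, non-lesional and healthy skin, with a black bar at the mean ± SD. TNFAIP6 averages 514 CPM in lesional and 28.3 CPM in healthy libraries.

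Non-lesional fibroblasts were set against healthy ones to ask what differs in uninvolved skin of the patients. PCOLCE2 rose by 4.50 ± 0.69, to 439 ± 99.7 CPM (SD, n = 4) from 29.2 ± 38.8 CPM (SD, n = 7). ABLIM1 rose by 2.01 ± 0.30, from 33.6 ± 13.9 to 134 ± 19.7 CPM. SPAG17 rose by 3.42 ± 0.57, from 4.54 ± 4.75 to 63.5 ± 23.4 CPM. These 3 were all that limma called (91, 70, 240.0 and 320.0 by the other 4 fits; adjusted p = 0.0148, 0.0148 and 0.0316), each higher in 4 of 4 libraries, with 902 genes nominal. Reticular dermis genes shifted up, with 1 of 12 past over all genes and 7 within the list, median 1.68 (camera, adjusted p = 6.09e-08; 0.218). MFAP5 (1.69), CD34 (1.68) and FBN1 (1.68) did not pass over all genes (adjusted p = 0.0674, 0.0674 and 0.102). Papillary dermis genes shifted down, with none of 11 past and 2 lower within the list, median -1.20 (adjusted p = 0.00172; 0.704). PTGDS stood at -4.23 (0.0869) and COL23A1 at -2.43 (0.210). Mural cell markers moved with them, with none of 10 past and 3 lower within the list, median -0.96 (adjusted p = 0.0166; 0.411). Of these, TAGLN stood at -2.30 (0.143) and TPM2 at -1.32 (0.212). SEMA3E, a guidance protein (3.42, adjusted p = 0.0575), and ADAMTSL4 (1.84, 0.0577) did not pass, nor did COL6A5 (0.78, 0.792, higher in 2 of 4), COL18A1 (-1.02, 0.474), CCL19 (-1.90, 0.488) and CCL2 (-0.45, 0.853, lower in 3 of 4). No gene passed without non-lesional 3, 11, 14 or 15, while 6 passed without healthy 10, 19 without healthy 13, 26 without healthy 4 and 74 without healthy 6; SPAG17 was also lost without healthy 9. The mural marker call was lost without healthy 6 (adjusted p = 0.0651) or non-lesional 15 (0.0543).

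Lesional and non-lesional fibroblasts, 4 libraries each, were compared for what marks the lesion within patients' skin, though the donor of each library is not labelled. Collagens shifted up in lesional skin, with a median log2 of 0.84 over 23 genes (camera, adjusted p = 4.34e-10; 0.0919). Papillary dermis genes shifted up too, median 2.29 over 11 (adjusted p = 8.89e-09; 0.236). The type 2 cytokine response had a median of 1.43 over 12 genes (adjusted p = 5.84e-07; 0.0532) and chemokines and cytokines 1.33 over 15 (adjusted p = 5.42e-06; 0.307). No single gene passed in limma, and 571 were nominal; the other 4 fits called 31, 30, 197 and 280.0. Adjusted within the list, 7 collagens, 5 papillary, 6 type 2 and 5 chemokine genes were higher. TNC stood at 5.06 (adjusted p = 0.127), COL6A5 at 4.81 (0.142), CXCL1 at 4.52 (0.144), COL13A1 at 2.85 (0.481), CCL26 at 3.05 (0.236), COL15A1 at 1.30 (0.360), ICAM1 at 1.84 (0.251), POSTN at 2.07 (0.481) and IL32 at 3.23 (0.516). The smallest p values were those of UGCG (1.43, adjusted p = 0.115), SERPINH1 (1.34, 0.115), the collagen chaperone, TYMP (1.65, 0.116) and CALR (1.12, 0.116). Of the 4 genes the study is known for, not independent evidence here, none passed over all genes and 4 within the list, median 2.73 (adjusted p = 3.54e-07; 0.0532). COL18A1 stood at 2.29 (0.236), CCL19 at 3.17 (0.505) and CCL2 at 2.18 (0.538). Metallothioneins had 2 of 7 higher within the list and a median of 1.08 (adjusted p = 5.52e-05; 0.307). MT1F stood at 1.99 (0.427). MHC class I genes had a median of 0.66 over 11 (adjusted p = 0.00216; 0.516). TAPBP stood at 0.74 (0.702). MHC class II genes had a median of 0.82 over 5 (adjusted p = 0.0443; 0.626), with HLA-DRA, also a myeloid marker, at 1.31 (0.63). Reticular dermis genes shifted down, 1 of 12 lower within the list, median -0.63 (adjusted p = 0.0297; 0.660). CD34 stood at -1.44 (0.348). The MHC class II call was lost without lesional 1 or 5 or non-lesional 14 or 15 (adjusted p = 0.0531 to 0.156) and the reticular call without lesional 7 or non-lesional 11, 14 or 15 (0.0595 to 0.293). By single genes, 1 passed without lesional 7 and 2 without non-lesional 14.

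Fibroblasts with UMIs of both COL6A5 and COL18A1, the cells the study is known for, were counted after thinning each cell to 1000 UMIs. They made up 7.19% ± 5.17 (SD, n = 4) of lesional fibroblasts, 0.508% ± 0.589 (SD, n = 4) of non-lesional ones and 0.333% ± 0.684 (SD, n = 6) of healthy ones. COL6A5 was seen, with or without COL18A1, in 16.8% of lesional and 0.823% of healthy fibroblasts, and COL18A1, with or without COL6A5, in 18.0% and 6.35%. In exact 2-sided permutation tests the pair gave p = 0.00952 for lesional against healthy skin (smallest possible 0.00476) and 0.738 for non-lesional against healthy skin. For lesional against non-lesional skin p was 0.0286, the smallest that 4 against 4 libraries can give. In these tests, 4 of 4 lesional libraries lay above each other group's mean. COL6A5 cells gave p = 0.00476 and COL18A1 cells 0.0429 for lesional against healthy skin in exact tests. As background, the pair was seen in 0.0834% of lesional keratinocytes and 0.0447% of lesional endothelial cells pooled, against 6.43% of lesional fibroblasts pooled. COL18A1 was seen in 8.37% to 10.4% of keratinocytes and 14.7% to 17.9% of endothelial cells. Thinning left out 1076 of 2573 lesional, 962 of 1792 non-lesional and 2609 of 4482 healthy fibroblasts. The lesional excess over healthy skin was 4.83 to 8.80 points with single libraries left out. That over non-lesional skin no longer passed without any 1 of the non-lesional libraries (6.51 to 6.87 points), and thinned to 2000 UMIs it was 9.97 points with an exact p of 0.10.

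Sub-clusters of fibroblasts were compared for a subpopulation of lesional skin. A sub-cluster led by PCOLCE2, C1QTNF3 and TNFAIP6 held 22.4% ± 5.73 (SD, n = 4) of non-lesional, 21.7% ± 11.7 (SD, n = 4) of lesional and 5.97% ± 3.34 (SD, n = 7) of healthy fibroblasts. A sub-cluster led by COL6A5, TNC, F13A1, IL32 and COL18A1, with CCL2 and POSTN, held 17.4% ± 10.2 of lesional, 1.98% ± 0.445 of non-lesional and 4.36% ± 5.00 of healthy fibroblasts. The first passed for non-lesional against healthy skin (exact p = 0.00303, adjusted p = 0.0212, higher in 4 of 4 libraries). For lesional against healthy skin neither passed, at an adjusted p of 0.0530 each (exact p = 0.00909 and 0.0152, higher in 4 of 4). Against non-lesional skin the second, at the smallest possible exact p (0.0286, adjusted p = 0.200), could not pass alone, though the libraries did not overlap. Most leading genes were among those left out of the clustering because they differed between groups. Without healthy 9 both passed for lesional against healthy skin (differences 15.1 and 14.8 points), and the non-lesional call was lost without any 1 of the non-lesional libraries (14.4 to 18.7 points over all left-out fits).

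Keratinocytes of lesional skin (4 libraries) were set against those of healthy skin (5 libraries). SERPINB4, a serpin of inflamed epidermis, rose by 5.91 ± 1.45, from 59.8 ± 87.6 to 1649 ± 1165 CPM. KRT16, a keratin of wounded and inflamed epidermis, rose by 4.58 ± 0.76, from 176 ± 153 to 3448 ± 1996 CPM. CA2 rose by 4.80 ± 0.46, from 21.8 ± 9.79 to 660.4 ± 215 CPM. The differentiation genes KRT2 (5.75 ± 0.80), KRT10 (2.42) and LY6D (3.94 ± 0.41) rose as well. SAA1, an acute phase protein, fell by 4.21, from 1044 ± 255 to 73.8 ± 60.5 CPM, and MGST1, a glutathione transferase that also marks sebocytes, from 1237 ± 369 to 128 ± 120 CPM. Of 5309 genes, limma called 337 (998, 993, 1049 and 1045 by the other 4 fits), 178 higher and 159 lower, and 1025 were nominal. Adjusted p was 4.87e-05 for CA2, 6.66e-05 for LY6D, 0.00121 for KRT2, 0.00269 for KRT16, 0.00331 for MGST1 (-3.80), 0.00718 for SAA1 and 0.0239 for SERPINB4, each with 4 of 4 libraries on its side. Further large rises were those of CRIP1 (4.16) and TPPP3 (5.27), both at an adjusted p of 0.00121. Further falls were those of ZBTB16 (-4.63, adjusted p = 0.000994), IL1R2 (-3.18, 0.00175), KRT8 (-3.44, 0.00175), which marks sweat glands, CHI3L1 (-4.02, 0.0189), WFDC2 (-3.64, 0.0199) and CYP27A1 (-3.17, 0.0329). Reads of KRT16 can be shared with KRT14 and KRT17 and those of SERPINB4 with SERPINB3.

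The keratinocyte markers rose as a group in lesional keratinocytes, with 11 of 18 higher and 1 lower over all genes, 15 and 1 within the list, median 1.46 (camera, adjusted p = 1.62e-11; 0.00184). They include KRT10, the stratifin gene SFN (1.92, adjusted p = 0.000839) and DMKN (2.12, 0.00121). Cornified envelope and filaggrin genes had 4 of 7 higher over all genes, 4 higher and 1 lower within the list, median 2.98 (adjusted p = 0.000139; 0.0786). Among them were CASP14 (2.98, 4.87e-05), KRTDAP (3.30, 0.00861) and CALML5 (3.07, 0.0150). Cell junction genes had 7 of 17 higher and 1 lower, 10 and 1 within the list, median 0.90 (adjusted p = 0.000109; 0.0786). Among them were the desmosome genes DSG1 (1.49, 0.00723), DSC3 (1.18, 0.0121) and JUP (1.03, 0.0112) and the connexin GJB6 (-1.44, 0.0117). Epidermal activation and alarmin genes had 4 of 14 higher, 6 within the list, median 3.17 (adjusted p = 0.000185; 0.451). Among them were SERPINB13 (4.97, 0.0183) and SPRR1B (4.05, 0.0286). Interferon response genes had 2 of 12 higher, 4 within the list, median 0.83 (adjusted p = 0.000657; 0.496). IFITM1 stood at 2.27 (0.0132) and IFITM3 at 1.74 (0.0260). The type 2 cytokine response had 2 of 6 higher over all genes and 2 within the list, CA2 and POSTN (2.88, 0.0239), median 0.75 (adjusted p = 0.00546; 0.168). MHC class I genes had none of 11 past over all genes and 4 higher within the list, median 0.96 (adjusted p = 0.000393; 0.496). TAP2 stood at 1.07 (0.0508) and B2M at 1.22 (0.0640). Metallothioneins had none of 7 past and 3 within the list, median 1.52 (adjusted p = 0.0120; 0.515). MT1G stood at 1.94 (0.0942). Sebocyte markers had 2 of 5 lower both over all genes and within the list, median -2.11 (adjusted p = 0.000971; 0.305), and include MGST1 and ACSBG1 (-4.74, 0.00573). Sweat gland markers had 1 of 5 lower, 2 within the list, median -0.94 (adjusted p = 0.0347; 0.305). Myeloid markers had none of 3 past, 3 higher within the list, median 1.90 (adjusted p = 0.0154; 0.407). HLA-DRA stood at 2.45 (0.0928).

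The cells behind this comparison differed in kind. The cluster led by CALML3, S100A2, KRT15, DAPL1 and SAA1, with MGST1, and the cluster led by KRT17 and GJB6, with LGR5, have follicular markers among their leading genes. Together they made up 67.7% to 85.4% of keratinocytes in the healthy libraries compared and 17.5% to 45.7% in the lesional ones. The first and larger has 1 such marker, KRT17, beside the basal genes KRT5 and COL17A1, so its follicular origin is not settled. The cluster led by SERPINB4, S100A7, S100A8 and KRT16 held 34.6% of lesional and 4.66% of healthy keratinocytes. Without the follicular clusters 37 genes passed, and with the fresh healthy library added 74; CA2, KRT16, LY6D and SFN kept their calls under every setting tried, and the other named genes lost theirs under at least 1. Healthy 4, 9, 12 and 17, the libraries low in HOX genes, are 4 of the 5 healthy libraries with at least 20 keratinocytes, so that the contrast could not be run without them. Leaving out 1 library gave 174 genes without lesional 1, 190 without lesional 2, 197 without lesional 7, 222 without healthy 9 and 202 without healthy 12. Of the named genes, WFDC2 lost its call without lesional 2 (adjusted p = 0.0603), CALML5 without lesional 5 (0.0529), CHI3L1 without lesional 2 or 5 (0.0777 and 0.0576) and SERPINB13 without lesional 1, 2 or 7 (0.0607 to 0.0717). SERPINB4 (0.0516 to 0.0745) and SPRR1B (0.0503 to 0.103) lost it in 6 of the 9 fits each, POSTN (0.0570 to 0.0792) and IFITM3 (0.0631 to 0.0799) in 5 and CYP27A1 in 8 (0.0510 to 0.134). The sweat gland call was lost without healthy 10 or 12 or lesional 5 (0.0563 to 0.0700) and the metallothionein call without healthy 12 (0.0503).

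**Figure D3:**
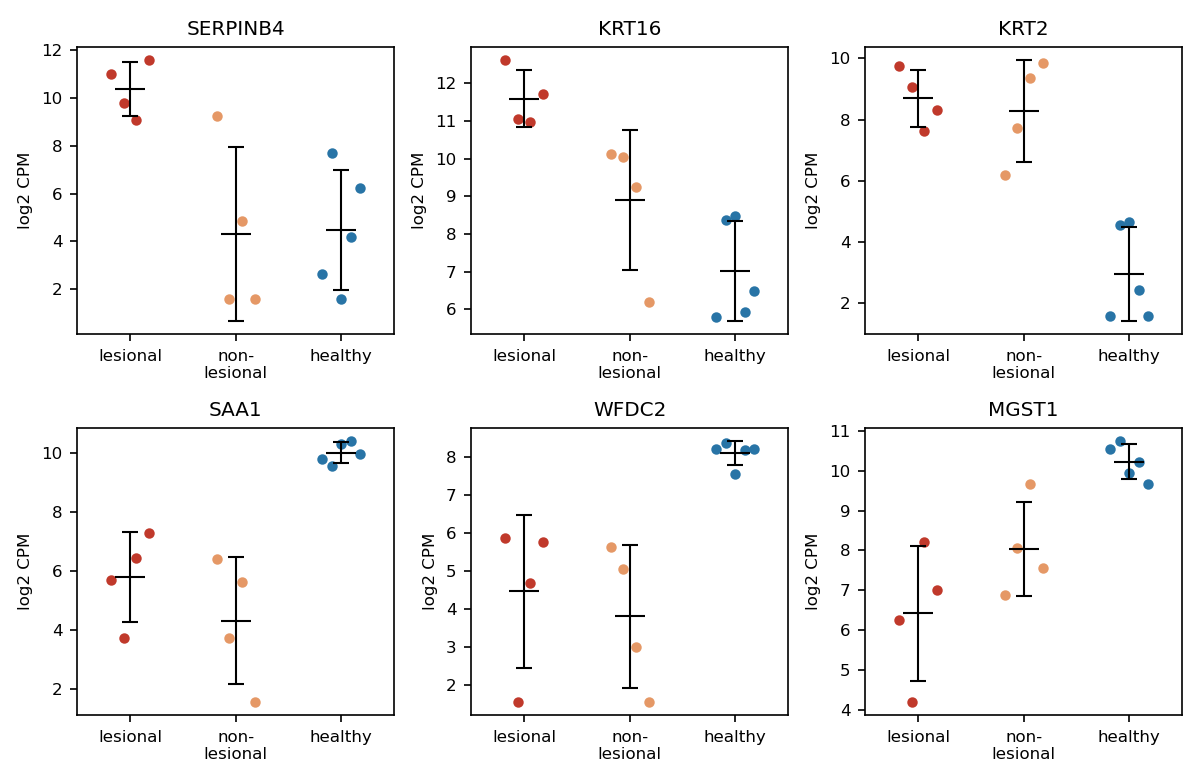
Level per library (log2 CPM, y axis) of SERPINB4, KRT16, KRT2, SAA1, WFDC2 and MGST1 in keratinocytes of lesional, non-lesional and healthy skin, with a black bar at the mean ± SD. KRT16 averages 3448 CPM in lesional and 176 CPM in healthy libraries.

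Sub-clusters of keratinocytes were compared in 4 lesional and 5 healthy libraries. A sub-cluster led by NNAT, CYP4F8 and PPARG held 0.621% ± 0.562 (SD) of lesional and 15.7% ± 4.27 of healthy keratinocytes. Another led by LGR5 and FRZB held 1.03% ± 0.882 and 13% ± 3.72. A cycling sub-cluster led by UBE2C and NUSAP1 held 18.2% ± 12.3 and 7.12% ± 1.42. All 3 passed (exact p = 0.00794 each, the smallest possible, adjusted p = 0.0265), with 4 of 4 lesional libraries on the same side. The cycling call was lost with only adjusted calls left out of sub-clustering, and its direction turned with no gene left out. A sub-cluster led by LTF, THBS2, POSTN and CCL2, 17.8% against 7.01% (exact p = 0.0238, adjusted p = 0.0595), and suprabasal cells, 23.2% against 13.3% (exact p = 0.0556, adjusted p = 0.111), did not pass, each higher in 4 of 4. With 1 library left out, each of the 3 calls was lost without lesional 2 or 5 or healthy 4, 9, 10, 12 or 17 (differences from -16.1 to -13.3, from -13.1 to -10.7 and from 4.98 to 13.6 points). The suprabasal share passed without lesional 1 (4.85 to 13.1 points over all fits) and the LTF share without lesional 7 (8.92 to 12.5).

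Non-lesional keratinocytes (4 libraries) against healthy ones (5) show the uninvolved epidermis. KRT10 rose by 3.55 ± 0.36, KRT1 by 3.46 ± 0.42, CASP14 by 3.43 ± 0.30, from 14.1 ± 4.0 to 185 ± 68.7 CPM, and KRT2 by 5.33 ± 0.80. SAA1 fell by 5.68, from 1044 ± 255 to 34.3 ± 36.8 CPM, and SERPINF1 by 4.18. In all, limma called 291 genes (970.0 with the log2 median UMIs per cell as a covariate), 141 higher and 150 lower, and 1202 were nominal. Adjusted p was 3.74e-05 for CASP14, 7.87e-05 for KRT10, 0.000444 for KRT1, 0.000719 for SERPINF1, 0.00154 for SAA1 and 0.00249 for KRT2, each with 4 of 4 libraries on its side. Other rises were those of CRIP1 (3.76), TPPP3 (4.38), KRTDAP (3.39) and CLEC2A (3.08). Other falls were those of IL1R2 (-3.92), WFDC2 (-4.29), CHI3L1 (-3.96), MSRB2 (-2.87), APMAP (-2.85) and KRT7 (-4.80), which marks sweat glands, with adjusted p from 0.000612 (IL1R2) to 0.0281 (KRT7 and APMAP). Keratinocyte markers had 11 of 18 higher, 13 higher and 1 lower within the list, median 1.59 (camera, adjusted p = 1.55e-12; 0.00113). DMKN stood at 2.77 (0.000183). Junction genes had 5 of 17 higher and 1 lower, 8 and 2 within the list, median 0.78 (adjusted p = 0.00105; 0.218). DSG1 stood at 1.71 (0.00450), DSP at 1.65 (0.00714), PKP1 at 1.63 (0.0104) and GJB6 at -1.68 (0.00633). Cornified envelope genes had 3 of 7 higher, 4 higher and 1 lower within the list, median 2.16 (adjusted p = 0.00172; 0.218). Immediate early genes had 1 of 17 higher both ways, JUND (1.21, 0.0120), median 0.58 (adjusted p = 0.00207; 0.797). Metallothioneins had 1 of 7 higher, MT1G (2.83, 0.0205), 2 within the list, median 1.66 (adjusted p = 0.00572; 0.708). Sebocyte markers had 1 of 5 lower, ACSBG1 (-4.12, 0.0142), 3 within the list, median -1.88 (adjusted p = 0.0172; 0.704). The cluster led by KRT1, KRT10 and DMKN held 18.5% of non-lesional and 2.23% of healthy keratinocytes pooled, so these rises were not separated from a shift between kinds of cell. The follicular clusters made up 25.7% to 31.9% of keratinocytes in the non-lesional libraries compared, without them 24 genes passed, and with the fresh healthy library added 5. The same 4 healthy libraries low in HOX genes stand here, and the count was 165 without healthy 9 and 120 without healthy 12. Calls lost with 1 library left out were those of CLEC2A (without healthy 12, adjusted p = 0.0523), ACSBG1 (healthy 4, 12 or 17, 0.0544 to 0.0814), CHI3L1 (healthy 12 or 17 or non-lesional 11, 0.0505 to 0.0546) and MT1G (healthy 9 or 12 or non-lesional 11, 0.050 to 0.0581). APMAP lost its call in 5 (0.0546 to 0.0595) and KRT7 in 7 (0.0521 to 0.0750) of the 9 fits. List calls lost were those of immediate early genes without non-lesional 11 (0.172), metallothioneins without non-lesional 11 (0.0691) and sebocyte markers without healthy 4 (0.0644) or non-lesional 3 (0.0567).

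Lesional against non-lesional keratinocytes (4 libraries each) show what the lesion adds. SPRR1B, an envelope protein that inflamed epidermis induces, was at least 150.4-fold higher in lesional skin, with 1835 UMIs over the lesional libraries and 0 over the non-lesional ones. It was the 1 gene past the threshold in limma (adjusted p = 0.0279, higher in 4 of 4), with 542 genes nominal. Epidermal activation and alarmin genes shifted up together, with 1 of 14 past, 7 within the list, median 3.80 (camera, adjusted p = 2.31e-07; 0.307). SERPINB4 stood at 6.08, KRT6A at 4.65 and KRT16 at 2.69 (adjusted p = 0.361 each). Interferon response genes had none of 12 past, 4 within the list, median 0.89 (adjusted p = 0.00381; 0.653). IFITM1 stood at 1.79 and IFITM3 at 1.69 (0.361 each). The type 2 cytokine response had none of 6 past, 1 within the list, median 1.24 (adjusted p = 0.0196; 0.307). CA2 stood at 2.65 (0.116) and POSTN at 1.42 (0.517). Immediate early genes had none of 17 past either way and a median of -0.11 (adjusted p = 0.0289; 0.787). JUND stood at -0.82 (0.371). Myeloid markers moved up beside these groups, 3 of 3 within the list, median 1.84 (adjusted p = 0.00540; 0.307) and HLA-DRA at 2.54 (0.415). Pooled, the cluster led by SERPINB4, S100A7 and KRT16 held 34.6% of lesional and 16.4% of non-lesional keratinocytes and that led by KRT1 and KRT10 2.96% and 18.5%, so shifts between kinds of cell were not separated from changes within them. MMP7 (4.61, 0.210), ZBTB16 (-3.61, 0.116) and LMO4 (-1.22, 0.120) did not pass. The SPRR1B call was lost without lesional 1, 5 or 7 or non-lesional 11 or 14 (adjusted p = 0.0641 to 0.207), with no low-count filter, a pseudocount of 0.5 UMIs, the other 4 fits or the naming rule as first fixed, and without the follicular clusters; 3 genes passed without non-lesional 3. The interferon and myeloid marker calls were lost without non-lesional 14 (0.0666 and 0.0897) and the immediate early call without lesional 1 (0.781), lesional 5 (0.0770) or non-lesional 11 (0.801), and the latter turned up with at least 10 cells per library (0.747).

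T and NK cells of lesional skin (4 libraries) were set against healthy skin (7). CCL1, the ligand of CCR8, had 8536 UMIs over the lesional and 0 over the healthy libraries, at least 1460.8-fold more when pooled. Lesional 5 was low (log2 CPM 5.07, where 0 UMIs give 3.42, against 12.2 to 13.3 in the others). TNFRSF18, the receptor GITR, rose by 1.55 ± 0.31, from 433 ± 160 to 1253 ± 374 CPM. TNFSF10 rose by 1.64 ± 0.30, from 215 ± 81.0 to 674 ± 218 CPM, and CRIP1 by 1.66 ± 0.23, from 3899 ± 821 to 12780.0 ± 4561 CPM. LTB fell by 1.37 on the log2 scale, from 3612 ± 985 to 1381 ± 377 CPM. Of 3918 genes, limma called 14 (220.0, 223, 326 and 365 by the other 4 fits), 13 higher and 1 lower, and 346 were nominal; the median log2 fold change of all genes was 0.175. Adjusted p was 0.00157 for CRIP1, 0.0147 for CCL1, 0.0275 for TNFSF10 and 0.0294 for TNFRSF18, LTB, LAIR2 (3.98) and PRDX1 (1.59). It was 0.0291 for NBAS (2.25) and 0.0390 for CSGALNACT1 (1.62), each with 4 of 4 libraries on its side. IL13, the type 2 cytokine, had 674 ± 203 CPM in lesional and 54.0 ± 75.8 in healthy skin but did not pass (4.29 ± 0.96, adjusted p = 0.0552, higher in 4 of 4). IL22 did not pass either (5.21 ± 1.47, adjusted p = 0.152, higher in 3 of 4). Cell cycle genes shifted up, with none of 11 past over all genes and 9 within the list, median 1.51 (camera, adjusted p = 1.87e-08; 0.168). Among them were TOP2A (2.61, 0.158), TYMS (2.45, 0.216), STMN1 (1.40, 0.178) and TUBA1B (1.15, 0.120). Regulatory T cell genes had 1 of 8 higher both ways, TNFRSF18, median 0.86 (adjusted p = 0.00163; 0.453). IL2RA stood at 2.16 (0.513), TNFRSF4 at 1.83 (0.488) and BATF at 0.85 (0.439). Genes of naive and recirculating T cells had 1 of 8 lower both ways, LTB, median -0.66 (adjusted p = 0.000148; 0.167). KLF2 stood at -1.17 (0.617), MAL at -1.12 (0.575) and TCF7 at -0.67 (0.683). Immediate early genes had none of 15 past, 1 lower within the list, median -0.44 (adjusted p = 0.00211; 0.496). FOSB stood at -1.38 (0.348) and JUNB at -1.25 (0.127).

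A sub-cluster of cycling T cells led by CCL1, UBE2C, RRM2 and TOP2A held 7.69% ± 4.44 (SD, n = 4) of lesional and 0.791% ± 0.986 (SD, n = 7) of healthy T and NK cells. It was higher in 4 of 4 libraries (exact p = 0.00606, adjusted p = 0.0424). Regulatory T cells, led by FOXP3 and IKZF2, held 9.20% ± 4.42 and 4.30% ± 3.96 (exact p = 0.0970, adjusted p = 0.339, higher in 3 of 4). The cycling call was lost without any 1 library except healthy 4 (5.07 to 8.70 points) and without the healthy libraries low in HOX genes (7.69 points, adjusted p = 0.400). CRIP1 kept its call in all 11 fits. CCL1 lost it without lesional 1, 2 or 7 (adjusted p = 0.0697 to 0.123), TNFSF10 without lesional 1, 2 or 7 or healthy 10 (0.0552 to 0.105), and the other named calls were lost in 6 to 8 of the 11. The count of 14 was 2 without lesional 1, 2 or 7, 5 without lesional 5, 4 without healthy 4, 3 without healthy 10 and 25 without healthy 17, and it was 2 with the log2 median UMIs per cell as a covariate.

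**Figure D4:**
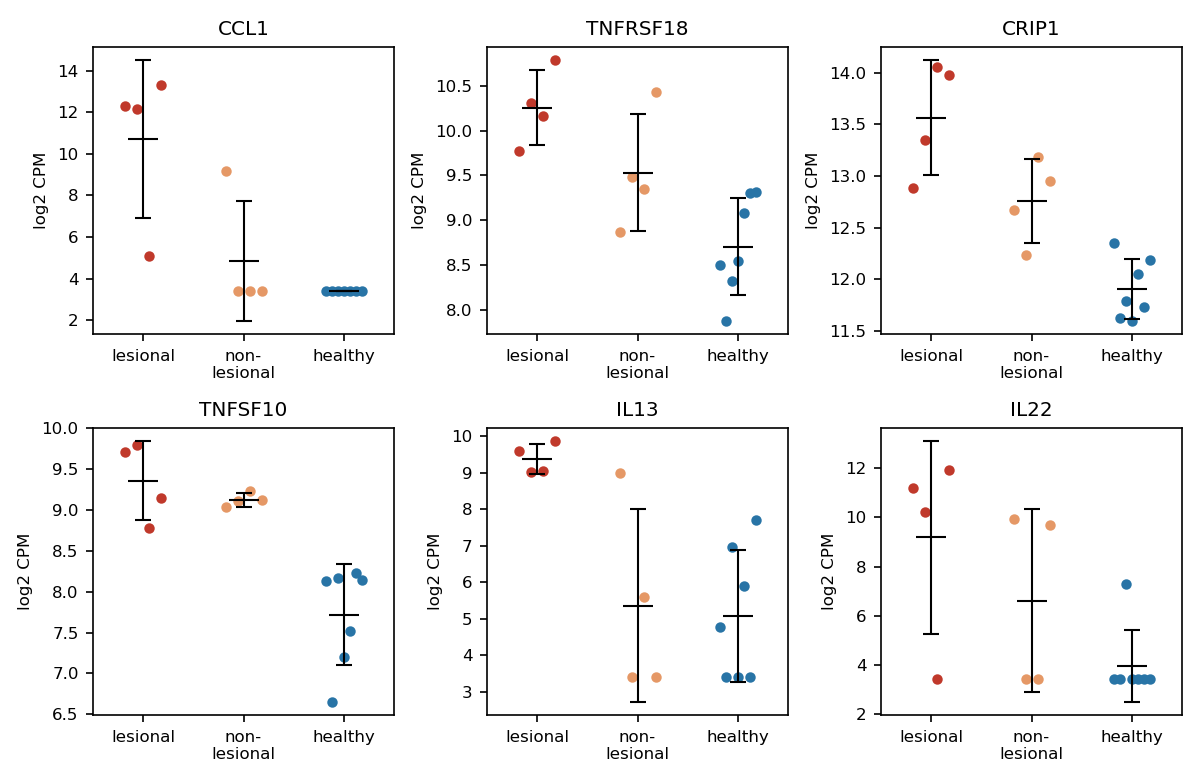
Level per library (log2 CPM, y axis) of CCL1, TNFRSF18, CRIP1, TNFSF10, IL13 and IL22 in T and NK cells of lesional, non-lesional and healthy skin, with a black bar at the mean ± SD. CCL1 has 0 UMIs in each of the 7 healthy libraries.

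In non-lesional T and NK cells (4 libraries) against healthy ones (7), SAT1 fell by 1.30, from 1344 ± 275 to 546 ± 160 CPM. It was the 1 gene limma called (27, 25, 31 and 66 by the other 4 fits; adjusted p = 0.0403, lower in 4 of 4), with 413 nominal. Immediate early genes shifted down, with none of 15 past and 6 within the list, median -0.71 (camera, adjusted p = 0.000131; 0.602). Among them were FOSB (-2.07, 0.105), DUSP1 (-2.07, 0.175) and JUNB (-1.49, 0.101). Genes of naive T cells shifted down too, with none of 8 past and 5 within the list, median -1.20 (adjusted p = 0.000836; 0.218). LTB stood at -1.34 (0.0667) and TCF7 at -1.06 (0.356). MRPL32 (-2.49) and EIF1 (-0.70) were at an adjusted p of 0.0667, and IL22 stood at 2.65 (0.547) and IL13 at 0.27 (0.936), each higher in 2 of 4 libraries. The regulatory sub-cluster differed by -0.909 points, and by 0.224 without non-lesional 11 and 0.297 without healthy 13. The SAT1 call was lost without healthy 4, 6, 9, 10 or 12 or non-lesional 16 (adjusted p = 0.0612 to 0.242), and with median-of-ratios factors, no low-count filter, a depth covariate, the marker score, or HOX-low libraries or the top 5% of doublet scores left out; 7 genes passed without non-lesional 3, 5 without non-lesional 14 and 2 without healthy 13.

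In lesional against non-lesional T and NK cells (4 libraries each), cell cycle genes shifted up, median 0.94 over 11 genes, 1 higher within the list (camera, adjusted p = 0.000377; 0.512). Regulatory genes had a median of 1.0 over 8, none within the list (adjusted p = 0.00817; 0.626). CTLA4, an inhibitory receptor, stood at 2.0 and TNFRSF18 at 0.72 (0.946 each). No gene passed in limma, with 154 nominal; the other 4 fits called 0, 0, 0 and 1. CCL1 stood at 5.85 ± 1.40 (adjusted p = 0.659), with 4945 ± 4172 CPM against 143 ± 285, IL13 at 4.02 ± 1.09 (0.946, higher in 4 of 4) and IL22 at 2.56 (0.946, higher in 3 of 4). TXNIP (-1.12), MRPL32 (2.42), TUBA1B (1.33), WSB1 (1.42) and STMN1 (1.15) had adjusted p from 0.659 to 0.946. The median log2 fold change of all genes was 0.196. Without non-lesional 3, 3 genes passed, and without lesional 5, 1.

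Myeloid cells were compared in 4 lesional and 5 healthy libraries; too few non-lesional libraries held 20 myeloid cells. Genes of mature dendritic cells, which carry antigen to lymph nodes, shifted up, with none of 17 past, 3 within the list, median 1.52 (camera, adjusted p = 8.57e-06; 0.429). Chemokines linked to type 2 inflammation shifted up too, with none of 10 past, 4 within the list, median 2.14 (adjusted p = 0.000277; 0.167). CCL13 had 1085 ± 832 CPM in lesional and 38.1 ± 44.2 CPM in healthy skin, and CCL18 1716 ± 2004 and 1.40 ± 3.12 CPM. No gene passed in limma; 428 were nominal, and the other 4 fits called 0, 6, 15 and 51. CCL13 (4.88) and CCL18 (6.48) were at an adjusted p of 0.129, CCL2 at 3.87 (0.134), CCL22 at 4.65 (0.578), and FCER2 at 2.70 (0.578). CD80 stood at 2.41 and CD274, the ligand PD-L1, at 2.73 (0.460 each), PALLD at 2.72 (0.460), LAMP3 at 2.25 (0.651) and CCR7 at 2.78 (0.668), each higher in 4 of 4. LILRB5 had 169 UMIs over the lesional and 0 over the healthy libraries, at least 15.1-fold more, and did not pass (adjusted p = 0.0834). Keratinocyte markers moved with these groups, none of 9 past and 4 within the list, median 2.01 (adjusted p = 0.00587; 0.515). KRT14 stood at 3.92 (0.596). This call was lost without healthy 4, 6 or 17 or lesional 1 or 7 (0.0528 to 0.121). The median log2 fold change of all genes was 0.303. Mature dendritic cells were 4.76% of lesional and 2.04% of healthy myeloid cells (exact p = 0.183, adjusted p = 0.365), and macrophages led by CCL18, LYVE1 and CCL13 25.1% and 10% (exact p = 0.119, adjusted p = 0.339). The chemokine rise was not separated from such shifts between kinds of myeloid cell.

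Vascular endothelium of lesional and non-lesional skin (4 libraries each) differed in 4 genes. ICAM1, a leukocyte adhesion molecule, rose by 1.96 ± 0.24, from 35.2 ± 12.4 to 142 ± 38.6 CPM. ADAMTS4 rose by 3.43 ± 0.52, HAPLN3 by 2.01 ± 0.34 and CRIP1 by 2.17 ± 0.38. By limma these passed (adjusted p = 0.00180, 0.0156, 0.0403 and 0.0491, each higher in 4 of 4), with 1056 genes nominal. Genes of endothelial activation and adhesion shifted up, with 1 of 17 past, 4 higher and 1 lower within the list, median 0.39 (camera, adjusted p = 0.00372; 0.307). SELE stood at 4.58 (0.155), VCAM1 at 2.31 (0.188), SELP at 1.43 (0.259) and ZBTB16 at -2.02 (0.0617). Capillary-like cells led by BTNL9 and CA4 made up 57.1% of non-lesional, 17.3% of lesional and 13.8% of healthy endothelium pooled. Non-lesional 11 gave 37.7% of them, and the rises were not separated from this shift. ICAM1 kept its call without any 1 of the 8 libraries and lost it with libraries of at least 10 cells. ADAMTS4 lost its call without lesional 1, 5 or 7 or non-lesional 3 (adjusted p = 0.0522 to 0.143), and HAPLN3 and CRIP1 in 6 fits each (the highest without lesional 7, 0.182 each). The count was 1 without lesional 1 or 7 or non-lesional 3 and 2 without lesional 5 or non-lesional 11.

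Lesional against healthy endothelium (7 libraries) gave no call in limma, with 563 genes nominal, while the other 4 fits called 7, 5, 19 and 9. Endothelial activation genes shifted up, with none of 17 past, 3 higher and 1 lower within the list, median 0.46 (camera, adjusted p = 0.00125; 0.168). SELE stood at 2.70 (0.53), IL6 at 2.33 (0.465), ICAM1 at 0.79 (0.465) and CX3CL1 at -1.31 (0.473). Interferon response genes had a median of 0.43 over 26, none within the list (adjusted p = 0.000148; 0.530). MX1 stood at 1.02, IFI6 at 0.99 (0.818 each) and IFITM3 at 0.51 (0.805). This call was lost without lesional 5 (0.732). Metallothioneins had a median of 0.79 over 4 (adjusted p = 0.0428; 0.515), immediate early genes 0.33 over 17 (adjusted p = 0.0257; 0.601) and lymphatic markers -0.51 over 3 (adjusted p = 0.0428; 0.360), with none past either way. MT1X stood at 1.08 (0.786). These calls were lost in 6 (the highest without lesional 2, 0.448), 4 (lesional 5, 0.811) and 7 (lesional 5, 0.744) of the 11 fits, and the last turned up with no low-count filter (0.948). MARCKS (-1.14), MOB3B (1.56), CRIP1 (1.81) and EMP1 (0.97) were at an adjusted p of 0.115 and STC1 at 3.04 (0.206), and 1 gene passed without lesional 2. In non-lesional against healthy endothelium limma called no gene, with 1258 nominal; the other 4 fits called 0, 0, 221 and 252. HAPLN3 (-1.77), CCDC3 (-1.22) and ICAM1 (-1.16) were at an adjusted p of 0.117, CERCAM at -2.15 (0.120) and MARVELD1 at -2.26 (0.146). Interferon response genes had none of 26 past, 2 higher within the list, median 0.43 (adjusted p = 0.000202; 0.797). MX1 stood at 1.41 (0.260), EPSTI1 at 1.24 and XAF1 at 1.03 (0.215 each). The call was lost without non-lesional 15 (0.311). Metallothioneins had a median of 1.06 over 4, none past either way (adjusted p = 0.0148; 0.708). MT1X stood at 0.98 (0.369), and the call was lost without healthy 4 (0.0644) or non-lesional 11 (0.319). Without non-lesional 14, 4 genes passed, and without non-lesional 3 or healthy 12, 1.

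Mural cells, the pericytes and smooth muscle of vessels, differed between lesional and non-lesional skin (4 libraries each) in 3 genes. TNFRSF12A rose by 3.31 ± 0.56, from 16.1 ± 11.2 to 232 ± 118 CPM. TNC rose by 2.11 ± 0.36, from 56.5 ± 16.2 to 273 ± 69.4 CPM, and COL1A1, collagen I, which also marks fibroblasts, by 1.66 ± 0.28, from 225 ± 77.0 to 730 ± 232 CPM. The test in limma gave all 3 an adjusted p of 0.0273, each higher in 4 of 4, with 494 genes nominal. Chemokines and adhesion genes shifted up, with none of 7 past, 4 within the list, median 2.03 (camera, adjusted p = 0.000137; 0.307). CCL26 stood at 2.83 (0.420), CCL2 at 2.33 (0.160) and VCAM1 at 2.02 (0.214). Endothelial markers moved the other way, none of 10 past and 3 lower within the list, median -1.68 (adjusted p = 6.39e-06; 0.421). Among them were CLDN5 (-3.51, 0.368) and PECAM1 (-2.81, 0.419). MAST4 stood at -1.89 (0.160). No gene passed without lesional 1 or 5 or non-lesional 3, 11, 14 or 15, 1 without lesional 7 and 25 without lesional 2, and none with no low-count filter, a pseudocount of 0.5 UMIs, or HOX-low healthy libraries or the top 5% of doublet scores left out. Against healthy skin (6 libraries), limma called no gene in lesional mural cells, with 301 nominal, and the other 4 fits called 18, 17, 10 and 3. Chemokines and adhesion genes again shifted up, with none of 7 past, 3 within the list, median 1.11 (adjusted p = 0.000657; 0.344). CCL26 stood at 3.36 (0.494), VCAM1 at 2.23 (0.221) and CCL2 at 1.30 (0.595). Metallothioneins had none of 6 past, 1 within the list, median 0.45 (adjusted p = 0.00252; 0.423). MT1A stood at 1.72 (0.287). Immediate early genes had a median of 0.27 over 17 (adjusted p = 0.0120; 0.515). ATF3 stood at 0.86 (0.49), a call lost without healthy 12 (0.0860) or lesional 5 (0.759). NABP1 (1.73, 0.183), ARID5B (1.01, 0.221), FRZB (-1.27, 0.221) and TUBB6 (0.98, 0.287) did not pass, and 1 gene passed without lesional 7. Non-lesional against healthy mural cells gave no call, with 522 genes nominal; the other 4 fits called 0, 1, 13 and 0. Endothelial markers stood higher, none of 10 past and 8 within the list, median 1.84 (adjusted p = 4.90e-07; 0.444). Among them were CLDN5 (2.95) and PECAM1 (2.63, 0.407 each). Mural markers had none of 15 past either way and a median of -0.63 (adjusted p = 0.00577; 0.218). PDGFRB stood at -1.04 and ACTA2 at -0.76 (0.439 each), a call lost without non-lesional 3 (0.141). Interferon response genes had a median of 0.30 over 17 (adjusted p = 0.00761; 0.708). IFI6 stood at 1.26 (0.421), a call lost without healthy 4 (0.0610) and turned down without the top 5% of doublet scores (0.881). A2M (1.15) and AGTR1 (1.68, 0.334 each), FOXS1 (-2.34), MRPL14 (-1.16) and RAMP1 (-1.53, 0.396 each) did not pass.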

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

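The tests in this part were chosen after the results were seen, except the random removal of keratinocytes. A library stood apart in 45 of 582 groups of 4 to 10 libraries (7.73%), where chance alone gives about 1 in 20: its gap to the nearest other library, divided by the range of the group, passed Dixon's 95% value. Of these, 42 were gene levels and 3 were shares. Healthy 9 stood high in the fibroblast sub-cluster led by COL6A5 (ratio 0.633; 14.6% against 0% to 5.37% in the others) and in fibroblasts with COL6A5 and COL18A1 (0.901; 1.72% against 0% to 0.170%). Lesional 2 stood high in the cycling keratinocyte sub-cluster (0.873; 36.5% against 10.7% to 14%). In keratinocytes, libraries stood high in ACSBG1 (lesional 7, 1.0; non-lesional 14, 1.0), CASP14 (lesional 1, 0.831), DSG1 (healthy 4, 0.731), IL1R2 (non-lesional 3, 0.904), KRT7 and MMP7 (non-lesional 14, 1.0 each), LMO4 (healthy 10, 0.777) and PKP1 (healthy 10, 0.816). They stood low in PKP1 (non-lesional 14, 0.858), SERPINB13 (lesional 5, 0.929), TAP2 (healthy 4, 0.872) and WFDC2 (healthy 10, 0.758). In fibroblasts, high values were those of ADAMTSL4 (healthy 6, 0.649), COL13A1 and CXCL1 (non-lesional 3, 1.0 each) and MT1M (healthy 17, 0.575). Low ones were CCL2 (healthy 13, 0.606), MT1A (healthy 10, 0.751), SEMA3E (non-lesional 11, 0.922), TAPBP (lesional 2, 0.938) and TPM2 (non-lesional 15, 0.839). In endothelium, EMP1 (lesional 5, 0.881), ICAM1 (non-lesional 14, 0.910), IFI6 (non-lesional 15, 0.905) and IFITM3 (lesional 5, 0.854) were high, and EMP1 (healthy 10, 0.592), MT1X (healthy 4, 0.662) and STC1 (healthy 13, 0.590) low. In mural cells CLDN5 (lesional 2, 0.833) and FRZB (lesional 1, 0.837) were high and PDGFRB (non-lesional 15, 0.882) low. In T and NK cells CCL1 (non-lesional 3, 1.0) and IL22 (healthy 9, 1.0) were high. Low there were CCL1 (lesional 5, 0.858), LAIR2 (lesional 5, 0.915; non-lesional 11, 0.850), MAL (non-lesional 11, 0.839), TNFRSF4 (healthy 6, 0.667) and TOP2A (lesional 5, 0.867). In myeloid cells CCL18 (healthy 9, 1.0) and FCER2 (healthy 6, 1.0) were high. A ratio of 1.0 means that the other libraries of the group had 0 UMIs.

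Data that no comparison used held 3 signals. The fresh healthy library held 92.5% keratinocytes and the frozen healthy libraries at most 33.3%. A cluster with no class name, led by SPP1, MSR1, MMP12, CCL1 and CCL22, held 5.28% of lesional 2 (97 of 1836 cells) and 0 cells of the other libraries. Another, led by HLA-DQB2, CD207 and CD1A, held 1.08% of the fresh library (48 of 4431 cells) and 0 of the others.

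The 159 lower and 178 higher genes of lesional against healthy keratinocytes were weighed first. Deeper cells are argued against: a depth covariate left 99.5% and 105% of the median change. Cell number as a cause was not tested. Random removal of as many cells as the follicular clusters hold left a median of 93 lower (48 to 124 over 20 draws) and 113.5 higher genes (30 to 165). Without the clusters 21 and 33 were left on the same genes, the 33 within the draws. The follicular clusters as the whole cause are argued against for the higher genes, which kept 83.5% of their median change without the clusters (75.6% to 88.6% with 1 library left out; 1.37 before, 1.14 after; median SE 0.303 and 0.375). For the lower genes they (the larger rests on KRT17 alone) cannot be told apart from a change within cells, as 75.4% was left (67.1% to 80.9%; -1.45 and -1.09; median SE 0.314 and 0.436); the calls that ended, all but 20 lower and 33 higher ones, did so with smaller changes and larger errors. Position on the body stays open too, as healthy 10 is the single healthy library here not low in HOX genes: it stood at 90.5% of the way from lesional to other healthy libraries for lower genes and 73.6% for higher ones, and disease itself stays open and untested.

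Healthy libraries 4, 9, 12 and 17 had HOX genes near 0 in fibroblasts. Too few UMIs are argued against, since at the lowest CPM of the others they would hold at least 42.1 HOX UMIs each and held 28, 3, 0 and 0. Biopsies from another position on the body may explain it: HOX genes in endothelium were at most 3.18 CPM in these libraries and at least 27.5 (lesional 7) or 144 CPM in the others. Mural cells had 26.7 to 163 CPM against at least 215, but keratinocytes of healthy 4 (122) lay above those of non-lesional 14 (117) and 15 (106).

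The larger share of lesional fibroblasts with both COL6A5 and COL18A1 was weighed against depth, free RNA, a single library and position. Thinning left 86.6% of the difference, lesional keratinocytes and endothelium held the pair in at most 0.0834% of cells, and the lowest difference without a lesional library was 4.83 points. Non-lesional skin, not low in HOX genes, reached 1.07% where the lowest lesional library had 1.34%. A lesional fibroblast state may underlie the share, as a hypothesis found and tested on the same data.

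Other splits of the same libraries were counted (100 drawn, or all where fewer, the real one included). No other split was as large for genes called in lesional against healthy keratinocytes (337; 1 of 100, highest other 41) and T and NK cells (14; 1 of 100, highest other 1). Nor was one in non-lesional against healthy keratinocytes (291; 1 of 100, highest other 53). This argues against chance, though shares were not corrected for their number. For fibroblasts under 0.05 of splits were as large against healthy skin, lesional (25; 3 of 100, highest other 104) and non-lesional (3; 4 of 100, highest other 46), which leaves chance and a structure of the samples open. Chance cannot be excluded for lesional against non-lesional endothelium (4; 1 of 35, the fewest possible, highest other 1), keratinocytes (1; 4 of 35, highest other 10) and mural cells (3; 2 of 35, highest other 6), non-lesional against healthy T and NK cells (1; 16 of 100, highest other 85), or the gene lists of lesional against healthy (34; 7 of 70, median and highest other 22 and 42), non-lesional against healthy (16; 14 of 56, 12 and 19) and lesional against non-lesional skin (19; 6 of 35, 12 and 24). Where no gene was called every split was as large: 35 of 35 for lesional against non-lesional fibroblasts and T and NK cells (highest other 1 each), and 100 of 100 for lesional against healthy endothelium (2), mural cells (3) and myeloid cells (3) and non-lesional against healthy endothelium (149) and mural cells (1). Splits with several times the real count point to a structure of the samples. They set apart lesional 7 with healthy 10, 12 and 13 (104), healthy 10, 12, 13 and 17 (46), non-lesional 11 with healthy 6, 10 and 13 (85) and non-lesional 3 and 15 with healthy 4 and 13 (149), and the highest of keratinocytes (41 and 53) healthy 4, 9, 12 and 17.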

How the results depend on the processing

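Tests chosen after the results were seen are those with other pseudocounts, voom or library weights, at least 10 cells, high doublet scores, HOX-low healthy libraries or follicular clusters left out, the naming rule as first fixed, and other gene sets for sub-clustering. LH, NH and LN stand for lesional against healthy, non-lesional against healthy and lesional against non-lesional skin. With settings other than leaving out a library, 151 counts of genes stayed within 1.5 times their value and 103 moved; 3431 named-gene results kept direction and side of the threshold, 296 lost and 269 gained a call and 2 reversed, as 1057 list calls were kept, 207 lost and 3 reversed, and 128 shares were kept, 10 weaker, 7 stronger and 12 reversed. Genes over 10-fold higher in another class left out, resolution 0.5 and no thinning moved no count or share result. Genes past the threshold became 2 (T and NK LH), 0 (fibroblast LH), 9 (keratinocyte LN) and 970.0 (keratinocyte NH) with a depth covariate. A pseudocount of 0.5 gave 7 (T and NK LH), 0 (fibroblast LH), 1 (fibroblast NH), 0 (keratinocyte and mural LN), 1 (myeloid) and 1 (endothelium LN), and a pseudocount of 5 gave 24 and 10 (T and NK LH, NH), 39 and 25 (fibroblast LH, NH), 3 (keratinocyte LN) and 2 (myeloid). By limma voom, its robust form, voom with library weights and limma with library weights in turn, counts were 220.0, 223, 326 and 365 (T and NK LH), 27, 25, 31 and 66 (NH), 259, 256, 470.0 and 614 (fibroblast LH), 31, 30, 197 and 280.0 (LN), 91, 70, 240.0 and 320.0 (NH) and 998, 993, 1049 and 1045 (keratinocyte LH). For mural LH they were 18, 17, 10 and 3 and for endothelium LH 7, 5, 19 and 9. The first 3 gave 0 in keratinocyte LN, the first 2 gave 9 in mural LN and 29 lists LN, and the last 6 in mural LN and 1 in T and NK LN. The last 2 gave 11 and 26 (endothelium LN) and 221 and 252 (NH), the last 3 gave 6, 15 and 51 (myeloid), and robust and weighted voom 1 and 13 (mural NH). At least 10 cells gave 3 and 5 (T and NK LH, NH), 219 (keratinocyte LH) and 0 (endothelium LN). Without the HOX-low libraries counts were 24 (T and NK LH), 14 and 10 (fibroblast LH, NH), 2, 0 and 2 (keratinocyte, mural and endothelium LN) and 3 lists NH; keratinocytes and the COL6A5 and COL18A1 share could not be compared with healthy skin. No low-count filter gave 1 and 0 (T and NK LN, NH), 8, 1 and 7 (fibroblast LH, LN, NH), 0 (keratinocyte and mural LN), 2 (endothelium LH) and 60 and 33 lists (LH, LN). T and NK NH fell to 0 with median-of-ratios factors, the marker score and the top 5% of doublet scores left out. The score also gave 9 (fibroblast NH) and 167, 2 and 129 (keratinocyte LH, LN, NH), and the doublet setting 14 (fibroblast LH), 0 (mural LN) and 2 (endothelium LN). Adding the fresh library gave 13 and 1 (fibroblast LH, NH), 74 and 5 (keratinocyte LH, NH), 3 (myeloid) and 1 (endothelium LN); leaving out follicular clusters 37, 0 and 24 (keratinocyte LH, LN, NH); and the first naming rule 0 (keratinocyte LN). Lists past the threshold were 2, 1 and 0 (LH, NH, LN) with an estimated correlation and 12, 5 and 2 with fry. Reversed results were IL13 in T and NK cells NH (-0.11 with at least 10 cells, from 0.27; -0.94, -0.03, -0.03 and -0.01 without non-lesional 3, healthy 6, 10 and 13, at most 0.92), CCL2 in fibroblasts NH (0.18 without HOX-low libraries, from -0.45), immediate early genes in keratinocytes LN (limma camera, adjusted p = 0.747, at least 10 cells), interferon genes in mural cells NH (0.881, doublet setting) and lymphatic markers in endothelium LH (0.948, no filter). Shares, in points, were without HOX-low libraries 9.66 (myeloid LH, no longer past), -5.04 (myeloid of immune NH, reversed), 7.69 (cycling T LH), 0.119 (COL6A5 fibroblasts NH, reversed) and 15.7 (PCOLCE2 fibroblasts NH). With 500 genes per cell they reversed to -0.506 (T and NK NH), 3.19 (endothelium NH), -3.38 (myeloid of immune NH) and 0.025 (PCOLCE2 LN), and were no longer past at 9.87 (cycling T LH), 19.6 (PCOLCE2 NH), -20.8, -14.0 and 6.30 (NNAT, LGR5 and cycling keratinocytes). Endothelium NH reversed to 2.87 with the fresh library and 0.753 without keratinocytes in the denominator, where T and NK NH was -3.70. Thinned to 2000 UMIs, the COL6A5 and COL18A1 share was 9.97 (LN, no longer past) and -0.103 (NH, reversed). With no gene left out of sub-clustering, COL6A5 and PCOLCE2 fibroblasts LH (16.3 and 23.8) and suprabasal and LTF keratinocytes (23.0 and 34.8) came past the threshold, and regulatory T cells NH (0.135) and cycling keratinocytes (-3.27) reversed; with only adjusted calls left out the first 3 were 15, 24.6 and 20.9, past it, and cycling keratinocytes 8.43, no longer. Leaving out 1 library, counts ran over 2 to 25, 0 to 3 and 0 to 7 (T and NK LH, LN, NH), 0 to 67, 0 to 2 and 0 to 74 (fibroblast), 174 to 337, 0 to 3 and 120.0 to 402 (keratinocyte), 0 to 1 and 0 to 25 (mural LH, LN), 0 to 1, 1 to 6 and 0 to 4 (endothelium), and lists over 26 to 39, 18 to 25 and 14 to 20. Shares ran over 8.36 to 10.6 (myeloid LH), 11.8 to 19.6 (myeloid of immune LH, past the threshold without healthy 6), -2.24 to 7.61 and -8.13 to 4.24 (T and NK, endothelium NH; the latter 0.196, 1.22, 0.576 and 4.24 without healthy 12, 13, non-lesional 15 and 16), 4.66 to 8.63 and -0.0112 to 0.454 (COL6A5 and COL18A1 LN, NH), 5.07 to 8.70 and -2.10 to 0.297 (cycling T LH, regulatory T NH), 9.13 to 16.6 (COL6A5 fibroblasts LH), 11.1 to 20.4, 14.4 to 18.7 and -5.39 to 3.95 (PCOLCE2 LH, NH, LN; 0.173, 3.95, 1.25 and 0.297 without lesional 1, lesional 7, non-lesional 14 and 15) and 4.85 to 13.1, 8.92 to 12.5, 4.98 to 13.6, -16.1 to -13.3 and -13.1 to -10.7 (suprabasal, LTF, cycling, NNAT and LGR5 keratinocytes). Fewer libraries make the smallest exact p larger, which ended calls of shares; otherwise the cause was not tested. The Wald test of DESeq2 and the fresh library for sub-clusters were not run, the filter on mitochondrial share had nothing to remove, and the 61 called doublets were kept throughout. In simulated data 2-fold changes were recovered for at most 12% of genes per class and 4-fold ones for 25.5% to 81%, so a low count can miss changes; depth and the number of libraries were not separated. No paired analysis was possible because the donor of each library is not labelled, and healthy n is too large if frozen healthy libraries share donors.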

Other observations

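The test of IL13 with IL22 was fixed before its result was seen; its background and doublet checks and the other genes, outside the rule for names, were chosen after. The hypothesis was that the same lesional T and NK cells make IL13 and IL22. Cells with UMIs of both were 85, 22 and 38 in lesional 1, 2 and 7, against 50.3, 12.5 and 20.5 expected from the single shares at matched depth. The lowest ratio was 1.69, and 1.66 without the top 5% of doublet scores, so the same cells may make both; lesional 5 had no IL22 cell. As background, the other 5 lesional classes compared had IL13 in at most 1.0%, IL22 in at most 1.33% and both in at most 0.5% of cells. IL9, IL4 and IL5 had 622, 10 and 7 UMIs in 2 of 4 lesional libraries and IL31 10 in 1, with 0 in other groups. IL17A had 37 UMIs in 2 of 7 healthy libraries and IL17F 4 in 1, with 0 in other groups.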
